A study of Mus musculus with 24 samples.

How the data were processed

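Gene expression was measured by RNA-seq in 24 libraries from mouse embryos, 4 for each of 6 genotypes. Per the labels' protocols, RNA from pharyngeal arches was made into indexed libraries with a stranded mRNA kit of Illumina. Per the submitters' processing notes, base calls came from CASAVA 1.8.2, reads were counted per gene with featureCounts, and the genome build was mm10. The aligner, the annotation release, the featureCounts version and its strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be assigned to either gene. The authors deposited raw counts per gene, with Entrez gene identifiers and gene lengths and no normalization, as 1 table of the series and as 24 files of single samples whose values were identical to the table's columns. Of 27179 entries, 568 had no gene identifier. They held 0.182% to 0.259% of the counts of a library and were left out of library sizes and tests. Of the 26611 identifiers, 25275 were matched to a symbol and the other 1336, with 0.573% of the counts, kept their number as name. Coordinates are from the RefSeq annotation of GRCm38, the assembly that mm10 names.

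Group, replicate number and batch were taken from the labels. The design text names 4 biological replicates per genotype and 2 mouse facilities as batches. The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts: genes were kept with filterByExpr by group (14506 genes), scaled by TMM, and fitted with robust quasi-likelihood dispersions in a model with 6 group means and a batch term over all 24 libraries (17 residual degrees of freedom, common biological coefficient of variation 0.0896). Each mutant group was compared with wild type, and the non-additive part was the double heterozygous value minus both single heterozygous values plus wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are on the log2 scale with standard errors derived from the test statistic, and levels are TMM-scaled CPM (counts relative to the scaled library total). A prior count of 2 was used for log2 CPM in plots, scores and principal components. Gene lists, 31 in all, covered arch patterning, signalling pathways, quality markers and the cell types the tissue can hold. The 30 with at least 4 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Design, lists, alternatives and the rule for named genes were fixed before the data were examined.

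The rule names Kat6a and the Dlx family always. It adds, per comparison, up to 10 called genes that rose and up to 10 that fell most, with a mean of at least 1 CPM and all 4 mutant libraries on the same side of all 4 wild type libraries after removal of the fitted batch effect, and up to 4 called members of each list. Predicted genes, pseudogenes and sex-linked markers were not picked by size. Postn outside the Dlx5 homozygous comparison, Zfp862-ps and Gm6402 fall outside the rule and were chosen after their values were seen.

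Dlx5 homozygous libraries shared no batch with wild type, so that comparison relies on the batch term. Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE scaling, no filter, a stricter filter (at least 1 CPM in 12 libraries), no batch term, batch 2 alone, only the groups compared, the replicate number as a block, and each library left out in turn. Length-corrected offsets, a neuron score as covariate, removal of neuron-rich libraries and removal of wild type replicate 4 in list tests were chosen after seeing the data, as were the fits that combine settings, the choice of genes for the dose slope with other wild type libraries and the regrouping of libraries within batch. The labels give no origin for the replicate numbers. Deviations from the group means correlated above 0.1 in all 4 same-numbered pairs of wild type and Kat6a homozygous labelled libraries (0.127 to 0.493) and of Kat6a heterozygous and Kat6a homozygous labelled libraries (0.179 to 0.54), so the numbers were taken to pair these groups, from the data alone. Some differently numbered pairs correlated more, so a pairing by number is not shown. Kat6a heterozygous replicate 4 reached 0.425 with Kat6a homozygous labelled replicate 3, against 0.179 with replicate 4. Wild type replicate 3 reached 0.144 with Kat6a homozygous labelled replicate 1, against 0.127 with replicate 3. In none of the other comparisons tested did all 4 pairs reach that level. The main model stayed without the block. Replicate pairs differed by 3.52 to 33.5 times the chi-square expected from sampling alone, so no library was counted as a duplicate.

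The procedure was tested on simulated counts with the real means, totals and dispersions and 200 changed genes among 14506. A further 15 or 16 members of the maxillary patterning list were raised, except for the non-additive part. Of genes changed 1.5-fold, 82.1% were recovered for the Kat6a homozygous comparison, 62.7% for Kat6a heterozygous, 74.6% for Dlx5 heterozygous, 65.7% for double heterozygous, 43.3% for Dlx5 homozygous and 52.2% for the non-additive part. Of genes changed 2-fold the shares were 86.6%, 91.0%, 76.1%, 79.1%, 70.1% and 83.6%. Between 4 and 10 unchanged genes were called. Simulated genes varied independently of each other, without the differences in neuron markers and gene length trend between the real libraries. The shares and the number of false calls may therefore not hold for the real libraries. At the lowest total, 10.4 M counts, 3 counts correspond to 0.288 CPM, and such limits cover counting error only. Part of the changes of 1.5-fold thus went undetected in every comparison, and smaller ones were not simulated. Figures were drawn with matplotlib 3.10.9.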

Results

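The series held 24 RNA-seq libraries, each made from the polyadenylated RNA of pharyngeal arches 1 and 2, the embryonic outgrowths that form the jaws and the middle and outer ear. All embryos were female mice at E10.5 on a C57BL/6 background. The libraries fell into 6 genotype groups of 4 biological replicates: wild type, Kat6a heterozygous, Dlx5 heterozygous, double heterozygous (1 mutant allele of each gene), Dlx5 homozygous and Kat6a homozygous. Kat6a, also called Moz, encodes a histone acetyltransferase, and Dlx5 encodes a homeodomain transcription factor of the lower jaw primordium. The title of the series gives the question as the effect of deleting either gene alone or both genes together on craniofacial development. Embryos came from 2 mouse facilities, given in the labels as batches. All 4 wild type and all 4 Kat6a homozygous libraries lay in batch 2, all 4 Dlx5 homozygous libraries lay in batch 1, and the 3 remaining groups spanned both. Total counts on genes ran from 10.4 to 28.2 M per library. The highest total belonged to wild type replicate 1 (28.2 M) and the next to Dlx5 heterozygous replicate 4 (16.7 M). Of the genes with an identifier, 14506 passed the filter on low counts and were tested.

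The targeted genes were examined first. Kat6a (Entrez gene 244349, chromosome 8, 22859442 to 22943259 in GRCm38) had 202 ± 41 CPM (TMM-scaled, mean ± SD, n = 4) in wild type, 234 ± 21 in Kat6a heterozygous libraries and 228 ± 15 in the libraries labelled Kat6a homozygous. The log2 fold change in the latter was 0.17 (SE 0.10, edgeR adjusted p = 0.474), so Kat6a counts were not lower there. Dlx5 (Entrez gene 13395, chromosome 6, 6877801 to 6882068) had 69.4 ± 6.8 CPM in wild type, 66.9 ± 7.5 in Dlx5 heterozygous libraries and 62.6 ± 5.1 in the libraries labelled Dlx5 homozygous. Its log2 fold change in the latter was 0.03 (SE 0.11, edgeR adjusted p = 0.947), and −0.15 without the batch term. The gene-level counts thus showed no called loss of either gene in the libraries labelled homozygous for it. They sum over the whole gene and cannot show a deletion of part of it, and exon counts were not used here. Directions given below for these groups are therefore directions in the libraries labelled as such.

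**Figure D1:**
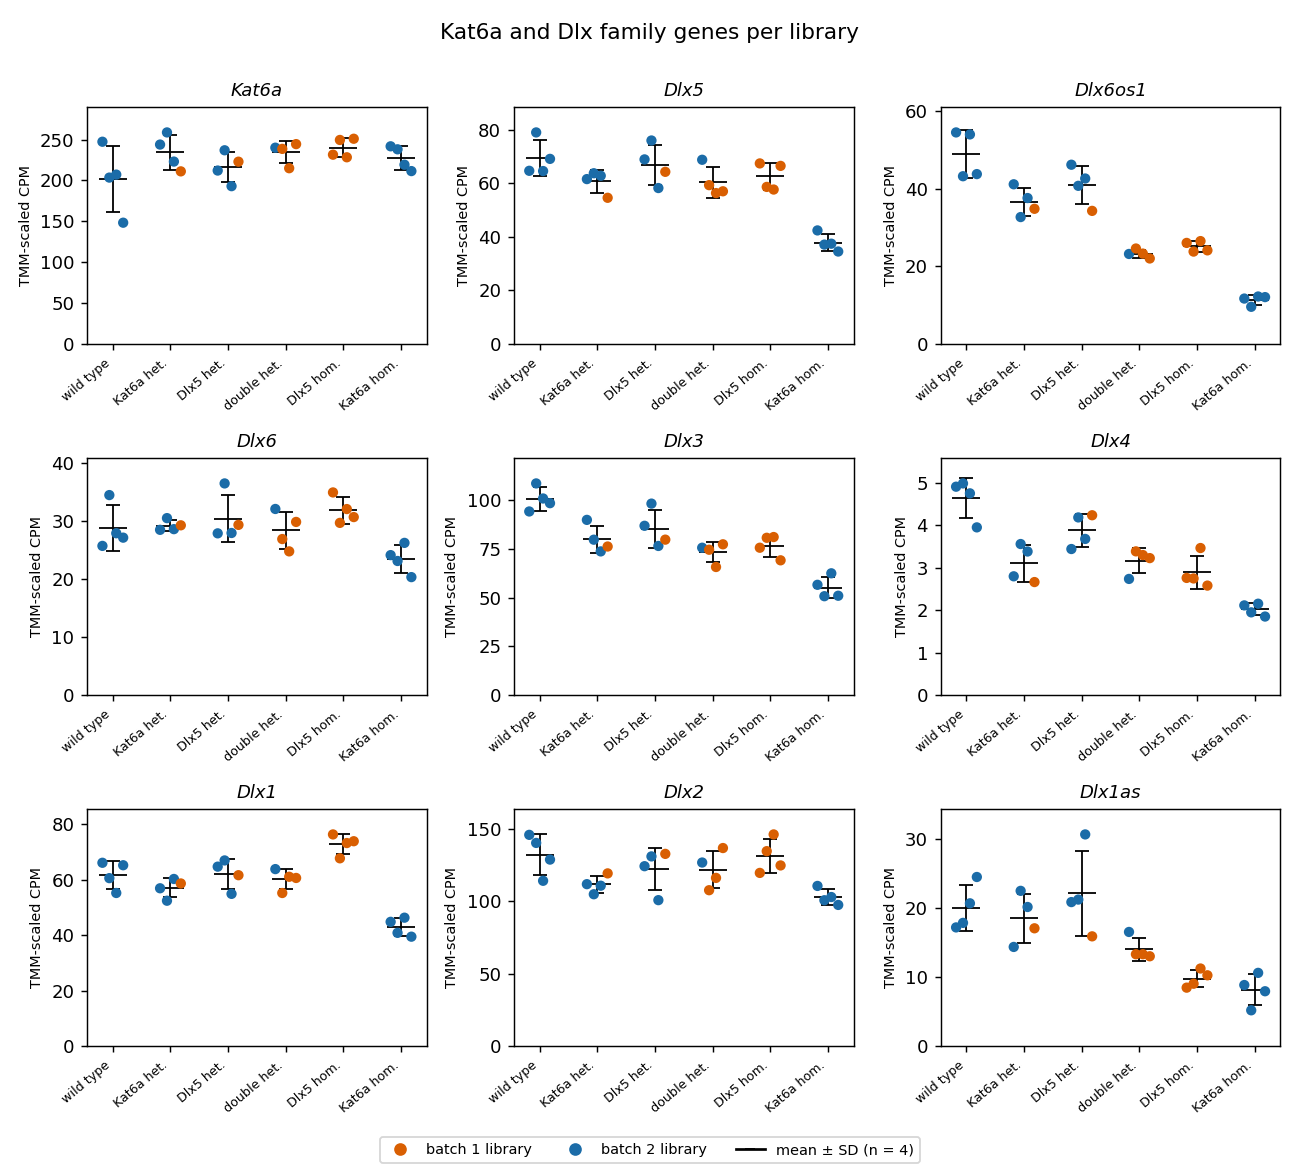
TMM-scaled CPM (vertical axes, starting at 0) of Kat6a and 8 Dlx family genes in each of the 24 libraries, by genotype group (horizontal axes). Points are libraries coloured by batch, and bars give the mean and SD of 4 libraries; Dlx6os1 lay at 48.8 CPM on average in wild type, at 23.3 in double heterozygous, at 25.1 in libraries labelled Dlx5 homozygous and at 11.4 in libraries labelled Kat6a homozygous, while neither Kat6a nor Dlx5 was called lower in the group labelled homozygous for it.

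In the libraries labelled Kat6a homozygous, 7 of the 8 genes tested in the Dlx family of homeobox genes and their antisense transcripts fell. The largest of these changes was in Dlx6os1, also called Evf2, a long noncoding RNA of the Dlx5 and Dlx6 locus (chromosome 6, 6820543 to 6871627), which fell from 48.8 ± 6.2 to 11.4 ± 1.2 CPM (SD, n = 4 and 4), a log2 fold change of −2.10 (SE 0.10, adjusted p = 1.52e-13). Dlx5 itself fell by 0.87 (SE 0.08, adjusted p = 1.46e-07), from 69.4 to 37.9 CPM, and Dlx3 by 0.86 (SE 0.08, adjusted p = 1.57e-07). Dlx4 fell by 1.21, Dlx1as by 1.29, Dlx1 by 0.53 and Dlx2 by 0.36 on the log2 scale, whereas Dlx6 stood at −0.29 (SE 0.10, adjusted p = 0.169). Thus 7 of 8 family members were called over all genes tested and 8 of 8 adjusted over the list alone. Dlx6os1 overlaps Dlx6 and Dlx1as overlaps Dlx1 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so the split of reads within each pair is uncertain.

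Outside the Dlx family, the largest falls in these libraries included genes at low levels. Six3, a regulator of the forebrain and eye, fell by 2.62 (SE 0.38, adjusted p = 0.000186) from a low level of 2.32 ± 0.50 CPM, and the protocadherin gene Pcdh8 fell by 2.65 (SE 0.38) from 1.96 ± 0.70 CPM. Nptx1, which encodes a neuronal pentraxin, fell by 1.90, Abhd15 by 1.82, Bhlhe22 by 1.54, Emx2 by 1.48 and Gbx2, a homeobox gene, by 1.43. Zmat4 fell by 1.42 and lies at 23647326 to 24063117 on chromosome 8, the chromosome that carries Kat6a. The odd-skipped genes Osr2 and Osr1, which act in palate and limb mesenchyme, fell by 1.71 and 1.18. The forkhead genes Foxc1 and Foxd1 fell by 0.56 and 0.60. Hoxb3, a gene of hindbrain and posterior arch identity, fell by 1.00 (SE 0.25, adjusted p = 0.0391). En2, a midbrain gene, fell by 2.31 (SE 0.59, adjusted p = 0.043) but from 0.848 ± 0.22 CPM. Smaller falls occurred in abundant genes: Col2a1, a cartilage collagen, by 0.28 from 936 ± 46 CPM, Crabp1, a retinoic acid binding protein, by 0.42 from 282 ± 41 CPM, and the nuclear receptor gene Nr2f2 by 0.33 from 201 ± 17 CPM.

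Among genes that rose in the same libraries, Mpo, the myeloperoxidase of granulocyte precursors, went from 3.15 ± 0.51 to 13.3 ± 3.2 CPM (SD, n = 4 and 4), a log2 fold change of 2.06 (SE 0.20, adjusted p = 2.31e-07). Stab2, a scavenger receptor of sinusoidal endothelium, rose by 1.35, Mrc1, the macrophage mannose receptor, by 0.88 and Gimap9 by 0.89, and Il2rg, a shared interleukin receptor subunit, rose from 0.998 ± 0.26 to 2.13 ± 0.49 CPM. The list of macrophage and leukocyte markers as a whole did not pass the test (1 of 12 rose, 3 rose and 1 fell adjusted over the list alone, adjusted p = 0.199). Elf5, an epithelial ETS factor, rose from the low level of 0.593 ± 0.16 CPM (adjusted p = 0.00275). Creb5 rose by 1.00, and Runx2, the regulator of bone formation, by 0.81 (SE 0.18, adjusted p = 0.0202), from 2.54 ± 0.17 to 4.46 ± 1.1 CPM. Has2, the main hyaluronan synthase of embryonic mesenchyme, rose by 0.35 from 39.2 ± 2.3 CPM, and Smad9 and Id2, genes responsive to bone morphogenetic protein, rose by 0.44 and 0.28.

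Over all genes, edgeR called 222 in this comparison, 68 higher and 154 lower, with a median absolute log2 fold change of 0.45 and 10 higher and 27 lower by more than 2-fold. Of 30 gene lists tested with camera, 6 were called. The Dlx family (adjusted p = 1.14e-60), mandibular arch patterning (5 of 24 fell, 9 adjusted over the list alone, median −0.18, adjusted p = 6.68e-11) and skeletal differentiation (1 rose and 2 fell of 12, 1 and 4 adjusted over the list alone, adjusted p = 0.0132) also passed with an estimated correlation (adjusted p = 9.33e-09, 0.0464 and 0.0464). The mandibular list shares Dlx3, Dlx4, Dlx5 and Dlx6 with the Dlx family, and Dlx5 is also in the skeletal list, whose other called members were Col2a1 (lower) and Runx2 (higher). The anterior Hox list (1 of 4 fell, 3 adjusted over the list alone) had adjusted p = 0.000283 and, with an estimated correlation, adjusted p = 0.0589. Myogenic markers (1 of 10 fell, the repressor Msc, and 2 adjusted over the list alone) had adjusted p = 0.0402, and the endothelin pathway (1 of 13 fell, Dlx5, and 2 adjusted over the list alone) adjusted p = 0.0402. Both were lost with an estimated correlation, at adjusted p = 0.0751 and adjusted p = 0.293, and both with the replicate block, at adjusted p = 0.0521 and adjusted p = 0.0607. With the replicate block and an estimated correlation, mandibular patterning (adjusted p = 0.0875) and skeletal differentiation (adjusted p = 0.0874) were lost too, and the Dlx family passed (adjusted p = 2.01e-07). Within batch 2 alone edgeR called 98 genes, 91 of them among the 222, and with only the libraries of these groups in the fit it called 64. limma voom called 144, and 83 were called with the neuron-rich replicate 2 of 4 groups left out. The count was 444 without wild type replicate 1, 142 without wild type replicate 2, 122 without Kat6a homozygous replicate 1 and 141 without Kat6a homozygous replicate 2.

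**Figure D2:**
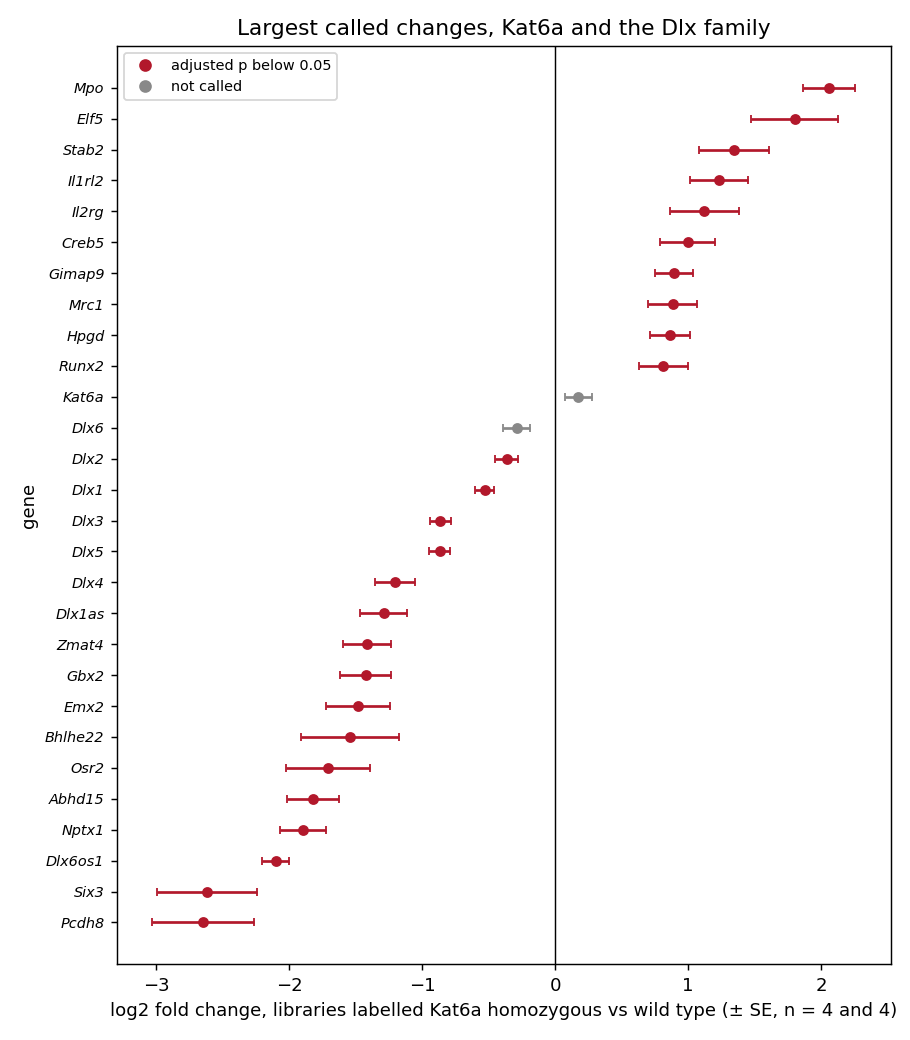
Log2 fold changes (horizontal axis, with SE bars) in the 4 libraries labelled Kat6a homozygous against 4 wild type libraries, for the largest called rises and falls, Kat6a and the Dlx family (1 gene per line), with points of adjusted p below 0.05 in red. Mpo lay highest at 2.06 and Pcdh8 lowest at −2.65, and Kat6a (0.17) and Dlx6 (−0.29) were not called.

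In Kat6a heterozygous libraries no single gene passed the test. Dlx6os1 stood at 36.5 ± 3.6 CPM (SD, n = 4), a log2 fold change of −0.39 (SE 0.09, adjusted p = 0.146). Dlx4 stood at −0.60 (SE 0.15, adjusted p = 0.146) and Dlx3 at −0.31 (SE 0.08, adjusted p = 0.173). For each of these 3 genes all 4 heterozygous libraries lay below all wild type libraries once the fitted batch effect was removed. Such a separation, in either direction, occurred in 675 of 14506 genes (4.65%, against 2.86% by chance), of which 0 were called. edgeR called 0 genes, with 1648 at an unadjusted p under 0.05, while DESeq2 called 80 (7 higher and 73 lower) and limma voom 0. Within batch 2 edgeR called 1 gene. Without wild type replicate 1 it called 196, of which 14 were called again with length-corrected offsets, without wild type replicate 3 it called 2 and without Kat6a heterozygous replicate 3 it called 1. By camera 8 lists were called. The Dlx family (0 of 8 fell, 4 adjusted over the list alone, median −0.21) had adjusted p = 8.38e-05 and, with an estimated correlation, adjusted p = 0.0872. Mandibular patterning, genes responsive to bone morphogenetic protein, endothelial, pharyngeal endoderm, eye and otic, and glycolysis and hypoxia genes lay lower, and subunits of Kat6a-type acetyltransferase complexes higher. With an estimated correlation each of these 7 lists had adjusted p = 0.245.

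In Dlx5 heterozygous libraries no Dlx family gene passed the test. Dlx6os1 stood at 40.9 ± 5.0 CPM (SD, n = 4; log2 fold change −0.23, SE 0.09, adjusted p = 0.329) and Dlx3 at 85.3 ± 9.6 CPM (−0.21, SE 0.08, adjusted p = 0.315). edgeR called 0 genes, with 1645 at an unadjusted p under 0.05, while DESeq2 called 31 and limma voom 0. Within batch 2 the edgeR count was also 0, and it was 1 without Dlx5 heterozygous replicate 4 and 1 without Kat6a homozygous replicate 2. With the neuron-rich replicate 2 of 4 groups left out it was 7, all higher. Palate and clefting genes (20 of 23 positive, 0 called, 2 adjusted over the list alone) and hedgehog responsive genes (12 of 15 positive, 0 called) lay higher by camera, at adjusted p = 0.00145 and 0.00761. Glycolysis and hypoxia, cell cycle and endothelial genes lay lower. None of these 5 passed with an estimated correlation, where glycolysis and hypoxia had adjusted p = 0.256, palate, hedgehog and endothelial genes adjusted p = 0.417 and cell cycle adjusted p = 0.517.

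In the libraries labelled Dlx5 homozygous, Dlx6os1 was again the gene with the smallest adjusted p. It fell to 25.1 ± 1.4 CPM (SD, n = 4), a log2 fold change of −0.82 (SE 0.13, adjusted p = 0.0116). Ptprz1, a receptor phosphatase of neural and glial cells, fell by 1.09 from 14.7 ± 2.9 to 8.08 ± 0.57 CPM, Cldn5, the tight junction claudin of endothelium, by 0.74 and Nudt19 by 0.57. Lix1 rose by 0.73, Creb5 by 1.46 and Postn, an extracellular matrix protein gene, by 0.51, from 28.4 ± 0.59 to 35.3 ± 2.2 CPM. The remaining called gene, Zfp862-ps, a pseudogene chosen after its values were seen, rose by 0.64. Among Dlx genes not called, Dlx4 stood at −0.75 (SE 0.21), Dlx1as at −0.66 (SE 0.24) and Dlx1 at 0.26 (SE 0.10).

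This comparison had no batch in common, so each of its values rested on the batch effect estimated from the 3 heterozygous groups, and no within-batch value exists. edgeR called 8 genes, 4 higher and 4 lower, with DESeq2 calling 38 (15 higher and 23 lower) and limma voom 17 (8 higher and 9 lower), and 13 were called with length-corrected offsets (5 higher and 8 lower). Without the batch term edgeR called 8 genes of which 2 were among these. Leaving out single libraries gave 0 to 16 genes. The count was 0 without double heterozygous replicate 1 or Kat6a heterozygous replicate 4, and 16 without Dlx5 homozygous replicate 3. It was 13 without wild type replicate 3, 14 without Kat6a heterozygous replicate 3 and 5 without Kat6a homozygous replicate 3. It lay between 1 and 3 without wild type replicates 1, 2 or 4, Kat6a heterozygous replicate 2, Dlx5 heterozygous replicates 2 or 4, double heterozygous replicates 2, 3 or 4, or Dlx5 homozygous replicates 1, 2 or 4. Neuron and glia markers were low in all 4 libraries labelled Dlx5 homozygous (centred log2 scores −1.59 to −1.19). Wild type replicates 1, 3 and 4 were about as low (−1.21 to −1.08), whereas wild type replicate 2 stood at 2.43. By camera 13 lists were called and none with an estimated correlation. Lower lists were the Dlx family (1 of 8 called, adjusted p = 0.00864), mandibular patterning, genes responsive to bone morphogenetic protein, p53 responsive, glycolysis and hypoxia, endothelial (1 of 12 called, Cldn5), epithelial, pharyngeal endoderm (0 called, 1 rose and 6 fell of 11 adjusted over the list alone) and neuron and glia genes (0 of 15 called, median −1.63). Higher lists were maxillary patterning, skeletal differentiation, hedgehog responsive and erythroid genes (0 of 12 called, median 0.79). With an estimated correlation the adjusted p was 0.227 for skeletal, endothelial and pharyngeal endoderm lists, 0.232 for the Dlx family and genes responsive to bone morphogenetic protein, 0.302 for maxillary, hedgehog, and glycolysis and hypoxia lists, 0.432 for p53, erythroid and epithelial lists, 0.499 for mandibular patterning and 0.571 for neuron and glia markers.

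In double heterozygous libraries Dlx6os1 fell to 23.3 ± 1.0 CPM (SD, n = 4), a log2 fold change of −0.96 (SE 0.11, adjusted p = 0.000107). The collagen genes Col6a3 and Col1a2 rose by 1.48 (12.6 ± 3.3 to 25.5 ± 7.9 CPM) and 0.66 (221 ± 31 to 284 ± 41 CPM), Runx2 rose by 1.13 and Creb5 by 1.39. The forkhead genes Foxl1 and Foxf2 rose by 1.47 and 0.76 and Pax9, a regulator of palate and tooth formation, by 0.84. Alkal2, a ligand of ALK family receptors, rose by 2.07 (SE 0.32, adjusted p = 0.00261), the glutamate receptor gene Gria1 by 1.96, the coagulation factor gene F13a1 by 1.57, Fibin by 1.42, Mpo by 1.36 and Cldn11 by 1.09. Kat6b, the closest relative of Kat6a, rose by 0.44 (SE 0.10, adjusted p = 0.044), from 53.9 ± 7.3 to 67.4 ± 3.4 CPM. This call was kept in 13 and lost in 23 of 36 alternative settings, and wild type replicate 4 had the lowest wild type level, 43.3 CPM. Falls included Aldh1a3, an enzyme of retinoic acid synthesis, by 2.32 (SE 0.48, adjusted p = 0.039), Six3 by 1.99, Hopx by 1.39, Foxi2 by 1.10, Rgl3 by 0.93, Ptprz1 by 0.86, Crb2 by 0.71, Nudt19 by 0.54 and Plpp2 by 0.52. These log2 fold changes are adjusted for the fitted batch effect, whereas the CPM means are not, and 3 of the 4 libraries lay in batch 1. The mean level of Mpo was 4.36 ± 1.8 CPM against 3.15 ± 0.51 in wild type, a smaller ratio than its log2 fold change gives. Dlx3 stood at −0.38 (SE 0.10, adjusted p = 0.0777) and Dlx5 at −0.07 (SE 0.09, adjusted p = 0.796). Neuron and glia markers were high in all 4 of these libraries (centred log2 scores 0.75 to 1.89), whereas in wild type only replicate 2 was high (2.43, against −1.21 to −1.08).

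edgeR called 65 genes in the double heterozygous libraries, 43 higher and 22 lower, against 185 by DESeq2 (92 higher and 93 lower) and 132 by limma voom (77 higher and 55 lower). Only replicate 1 lay in batch 2 with the wild type, and within batch 2 edgeR called 9 genes, 3 of them among the 65. Without the batch term 10 genes were called. With the neuron score as a covariate 16 of the 65 and no others were called, and with the neuron-rich replicate 2 of 4 other groups left out 138 were called (114 higher and 24 lower). The count was 1 without double heterozygous replicate 1, 24 and 21 without replicates 2 and 4, 169, 103 and 13 without wild type replicates 1, 3 and 4, 105 and 11 without Kat6a heterozygous replicates 1 and 4, and 31 without Dlx5 heterozygous replicate 4. By camera 9 lists were called, none with an estimated correlation. Hedgehog responsive genes (14 of 15 positive, 1 called, 2 adjusted over the list alone), palate and clefting genes (2 of 23 called, 3 adjusted over the list alone), maxillary patterning, macrophage and leukocyte (0 of 12 called, median 0.36) and neuron and glia genes (0 of 15 called, median 1.23) lay higher. The Dlx family (1 of 8 called, 3 adjusted over the list alone), glycolysis and hypoxia, epithelial and pharyngeal endoderm genes lay lower, although the called endoderm gene, Pax9, rose. With an estimated correlation the adjusted p was 0.0825 for the Dlx family (3.62e-05 with the preset one), 0.125 for hedgehog and for glycolysis and hypoxia genes, 0.208 for palate and clefting, 0.363 for macrophage and pharyngeal endoderm, 0.404 for maxillary, 0.593 for epithelial and 0.648 for neuron and glia genes.

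The double heterozygote was also compared with the sum of the single heterozygous effects on the log2 scale. For Dlx6os1 the departure from additivity was −0.35 (SE 0.13, adjusted p = 0.877), and for Dlx3 it was 0.14 (SE 0.11, adjusted p = 0.907). edgeR called 1 gene, with 783 at an unadjusted p under 0.05, DESeq2 1 and limma voom 0. The gene was Gm6402, a transcribed pseudogene (log2 departure 1.24, SE 0.20, adjusted p = 0.032), which was chosen after its values were seen because it was the only call. It stood at 14.5 ± 2.3 CPM in wild type and 16.7 ± 2.7 in the double heterozygotes (SD, n = 4 each), and its log2 fold changes in the Kat6a and Dlx5 heterozygotes were −0.50 (SE 0.15) and −0.44 (SE 0.14). Its reads can be shared with related copies, so its level is uncertain. Within batch 2, which holds 1 double heterozygous library, edgeR called 6 genes, none of them Gm6402, with the lone library assumed to vary like the other groups. The call was lost (0 genes) without wild type replicates 1, 3 or 4, Kat6a heterozygous replicates 1, 2 or 4, Dlx5 heterozygous replicates 3 or 4, double heterozygous replicates 1 or 3, or Dlx5 homozygous replicates 3 or 4. By camera 8 lists were called and none with an estimated correlation (adjusted p = 0.148 for endothelial and stress response genes, 0.541 for the other 6).

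The overlap between genotypes was counted next. Of the 222 genes called in the libraries labelled Kat6a homozygous and the 8 in those labelled Dlx5 homozygous, 3 were shared in the same direction: Dlx6os1 fell and Postn and Creb5 rose in both. Independent lists of these sizes share 0.0188 higher and 0.0425 lower genes on average, and 20 simulations of unchanged groups against the same wild type libraries shared 0, which is no chance value for lists of this length, since unchanged groups have no effects to call. With the wild type libraries split 2 and 2 between the comparisons, the shared count ran from 0 to 3. The libraries labelled Kat6a homozygous and the double heterozygous libraries shared 18 called genes (12 higher and 6 lower, against 0.202 and 0.234 for independent lists), among them Dlx6os1, Six3, Runx2, Mpo, Creb5, Postn and Col6a3 (Postn in these libraries was chosen after its values were seen), and 1 to 8 with split wild type libraries. The Dlx5 homozygous labelled and double heterozygous libraries shared 6 (3 higher and 3 lower, against 0.0119 and 0.00607 for independent lists, and 0 to 5 with split wild type libraries): Lix1, Postn and Creb5 rose and Dlx6os1, Ptprz1 and Nudt19 fell in both. Across 9890 genes the log2 fold changes of the homozygous groups had a covariance of 0.0104 against 0.0052 ± 0.00047 (SD) simulated from shared controls alone. With split controls the covariance was 0.00175. Their correlation was 0.41, against 0.35 simulated and 0.06 on average with split controls (−0.07 to 0.24). For Kat6a homozygous labelled and double heterozygous libraries the covariance was 0.00925, against 0.0053 ± 0.00046 (SD) simulated and 0.00171 with split controls, and the correlation 0.38 lay below the simulated 0.39. For Dlx5 homozygous labelled and double heterozygous libraries the covariance was 0.0223, against 0.0128 ± 0.00069 (SD) simulated and 0.0143 with split controls, and the correlation 0.71 against 0.69. With split controls this correlation was 0.38 on average (0.19 to 0.67). Both comparisons rest on the same fitted batch term, which splitting the controls does not remove. Genes are not independent replicates. Simulated genes varied independently of each other, without the differences in neuron markers and gene length trend between the real libraries. The simulated values and SDs thus leave out variation shared between genes and cannot show that a covariance lies beyond it.

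The size of the heterozygous effect was expressed as a slope on the homozygous one, with different wild type libraries in each. Over the 222 genes called in the libraries labelled Kat6a homozygous, the heterozygous change was 0.303 times the homozygous change (SD 0.087 over 6 assignments of wild type libraries), and on average 183 of 222 genes (82.6%) had the same direction. These genes were chosen with all 4 wild type libraries, which favours a positive slope: 20 simulations with an unchanged heterozygote gave 0.0461 (SD 0.0451) and 59.8% in the same direction. Here too simulated genes varied independently of each other, so the simulated SDs leave out variation shared between genes. Genes were also chosen against 2 wild type libraries, with the heterozygote set against the other 2. The slope then ran from 0.106 (1291 genes) to 0.361 (80 genes). Over the 6 assignments 1105 of 1755 genes (63.0%) had the same direction, a gene counting once in each assignment that called it. The assignment with wild type replicates 2 and 4 in the homozygous contrast held 1291 of these genes, 793 of them in the same direction. Over the 8 genes called in the libraries labelled Dlx5 homozygous the slope was 0.526 (SD 0.051), against 0.0601 (SD 0.0949) simulated. With genes chosen in that other way it was 0.188 on average, from 0.0572 (486 genes) to 0.312 (7 genes), and 2 of the 6 assignments called no gene. Over all assignments 233 of 501 genes (46.5%) had the same direction. The assignment with wild type replicates 2 and 4 in the homozygous contrast held 486 of these genes, 218 of them in the same direction. The other assignments with calls gave 2 of 2, 7 of 7 and 6 of 6 genes. The direct comparison of both Kat6a genotypes, whose contrast holds no wild type library, was added after the data were seen. edgeR called 93 genes there, 17 higher and 76 lower in the libraries labelled homozygous, with Dlx6os1 at −1.72 (SE 0.10, adjusted p = 5.04e-11) and Dlx5 at −0.72 (SE 0.08, adjusted p = 1.17e-05). With only these 2 groups in the fit it called 32 genes, and with the replicate block added 334, 71 of them among the 93. Those 334 were balanced, 174 higher and 160 lower, on 2 residual degrees of freedom, so the excess of lower genes did not hold in that fit. It did hold with the block over all libraries (14 residual degrees of freedom), which called 106 genes, 22 higher and 84 lower, 87 of them among the 93.

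**Figure D3:**
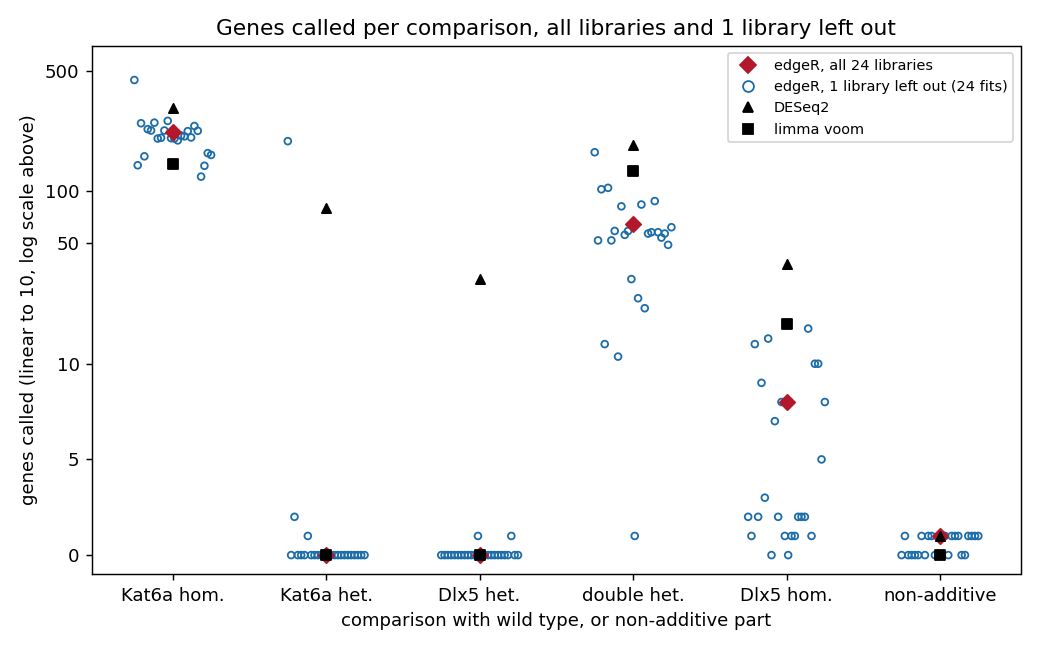
Genes called at an adjusted p below 0.05 (vertical axis, linear to 10 and logarithmic above) in each of 6 comparisons (horizontal axis). Diamonds are the edgeR counts with all 24 libraries (222, 0, 0, 65, 8 and 1), open circles the 24 fits with 1 library left out, triangles DESeq2 and squares limma voom; the count for libraries labelled Kat6a homozygous ran from 122 to 444 and that for double heterozygous libraries from 1 to 169.

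Markers of cells other than arch mesenchyme varied between libraries of the same group. The first principal component of log2 CPM held 24.8% of the variance and followed neuron and glia markers, whose scores were 2.43, 2.57, 2.25 and 1.68 in replicate 2 of the wild type, Kat6a heterozygous, Dlx5 heterozygous and Kat6a homozygous labelled groups. Wild type replicate 4 had a slope of −0.17 in log2 CPM per log2 gene length, while the other 23 libraries lay between −0.04 and 0.09. Across genes, the log2 fold changes correlated with gene length in each comparison with wild type (Spearman coefficients across genes, which are not independent replicates, of 0.184 for Kat6a homozygous labelled, 0.394 for Kat6a heterozygous, 0.146 for Dlx5 heterozygous, 0.325 for double heterozygous and 0.28 for Dlx5 homozygous labelled libraries). With length-corrected offsets the 5 counts were 330, 0, 0, 70 and 13, and 201 of the 222 and 54 of the 65 genes were called again. For Kat6a homozygous labelled libraries the replicate block with these offsets gave 434 genes, 206 of the 222 among them.

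**Figure D4:**
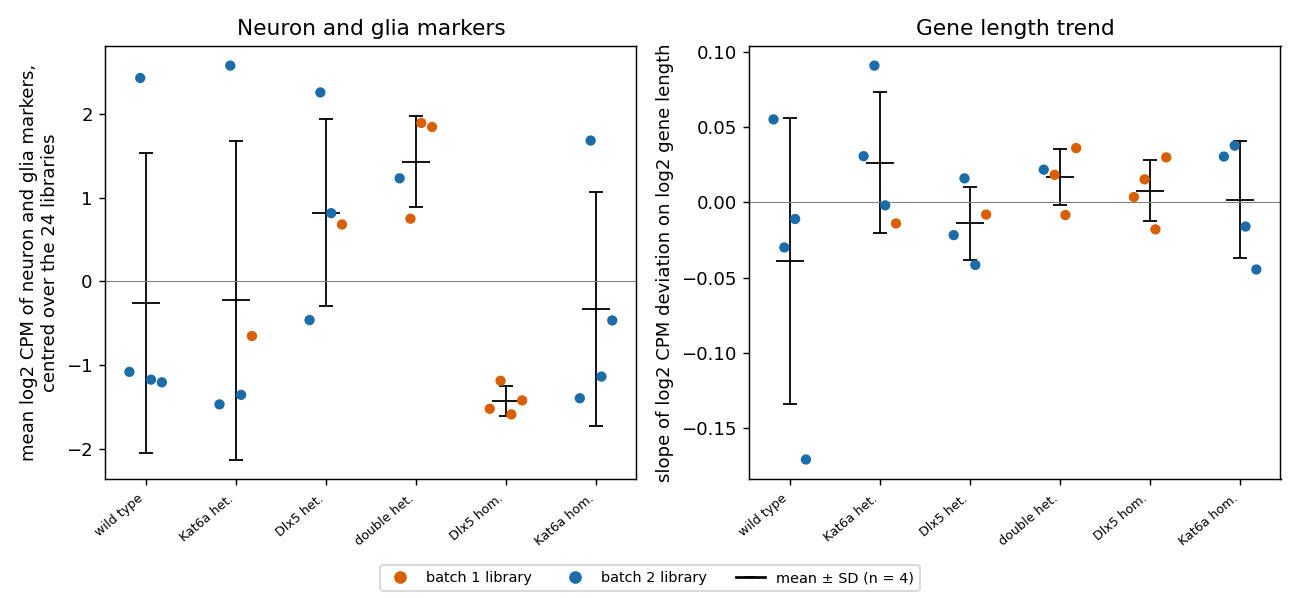
Left, mean log2 CPM of neuron and glia markers, centred over the 24 libraries (vertical axis), by group (horizontal axis), and right, slope of each library's log2 CPM deviation on log2 gene length. Points are libraries coloured by batch, and bars give the mean and SD of 4; the double heterozygous libraries all lay above 0 for neuron markers and the Dlx5 homozygous labelled ones all below, and wild type replicate 4 had the lowest length slope, −0.17.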

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

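The tests of gene length, neuron content, the batch term, the targeted genes and other splits of the samples were chosen after the result was seen.

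Single libraries stood apart from the other 3 of their group by a gap test that chance alone passes in about 1 of 20 groups, and 9 of 132 groups did so. Total counts were 28.2 M in wild type replicate 1 and 16.7 M in Dlx5 heterozygous replicate 4. Dlx6 stood at 36.5 CPM in Dlx5 heterozygous replicate 2 and Dlx1as at 16.5 CPM in double heterozygous replicate 1. Mean log2 CPM of erythroid markers was 4.71 in Kat6a heterozygous replicate 4 and 6.64 in Kat6a homozygous replicate 4. Neuron and glia markers stood at 4.46 in wild type replicate 2, and in double heterozygous replicate 1 cardiac and outflow tract markers stood at 1.84 and pharyngeal endoderm markers at 2.20.

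The double heterozygote differed from the sum of the single heterozygous effects, by the test of the non-additive term, for Gm6402 (1.24 on the log2 scale) and for 8 lists. Their median departures were 0.14 for mandibular patterning, 0.10 for neural crest and arch mesenchyme, 0.13 for genes responsive to bone morphogenetic protein, 0.0705 for cell cycle, 0.23 for stress response, 0.20 for endothelial, 0.37 for macrophage and leukocyte and −0.34 for epithelial genes. None of these lists passed with an estimated correlation (adjusted p = 0.148 to 0.541), and the call of Gm6402 was lost (0 genes) in 12 of the 24 fits with 1 library left out.

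Other splits of the same libraries into groups of 4 argued against chance for 1 count, provided that same-numbered libraries are not pairs. The shares were not adjusted for the number of counts examined, and 1 of 35 is the smallest share that 35 splits can give. For the libraries labelled Kat6a homozygous 1 of 35 splits, the real one, gave 222 genes, and the highest other gave 2. Of the 8 splits that part all 4 same-numbered pairs, too few for a share under 0.05, the real one gave 222 and the highest other 0, and the 27 that part fewer gave at most 2. For double heterozygous libraries 1 of 35 splits, the real one, gave 65 genes and the highest other 0, but only 5 of these splits keep the batches of the real groups, too few for a share under 0.05. For the Dlx5 homozygous labelled libraries (real 8, highest other 37, 3 of 35 splits as large) only the real split, which follows batch, keeps them, and no within-batch value can be had. For the non-additive count (real 1) the kinds of split disagreed, so chance is left undecided. Of splits drawn over both batches, 9 of 100 were as large (highest other 601). With libraries regrouped within batch 4 of 100 were (highest other 44), a share under 0.05. With a real count of 0, all 35 of 35 splits are as large for Kat6a heterozygous (highest other 178) and Dlx5 heterozygous libraries (highest other 12), so these counts decide nothing. What made the splits that called 178 and 601 genes stand out was not tested. The former sets wild type replicate 1 with Kat6a heterozygous replicates 1 to 3 against the other libraries. The latter puts 3 batch 1 libraries on the wild type side, but other drawn splits that do so called 0 to 21 genes. For counts of lists chance could not be excluded for Kat6a homozygous labelled (real 6, highest other 12, 9 of 35 splits), Kat6a heterozygous (8, 11, 7 of 35) and Dlx5 heterozygous libraries (5, 15, 16 of 35) or the non-additive term (8, 13, 25 of 100, and 11 of 100 within batch). Too few splits keep the batches for the lists of double heterozygous (9, 13, 6 of 35) and Dlx5 homozygous labelled libraries (13, 13, 2 of 35).

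Kat6a heterozygous libraries gave 0 genes with all libraries and 196 without wild type replicate 1, the deepest library. The tables argue against its depth, since thinning it to the depth of the other libraries gave at most 0 genes in 5 draws, and against neuron content, since in the fit without it the neuron score left fold changes at a slope of 1.00 and all 196 genes called. Gene length remains open: length-corrected offsets in that fit left 14 of the 196 called, at a slope of 0.77, and calls ended because the median absolute log2 fold change went from 0.36 to 0.25, while the median SE was 0.08 before and after. A shift of the remaining 3 wild type libraries may also account for the calls, but the slope test on it (0.35) cannot tell it from an effect shared by both heterozygous groups, which were compared with the same 3 libraries. An effect of Kat6a dosage remains open as well.

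The 65 genes called in double heterozygous libraries coincided with high neuron markers and with 3 of 4 libraries in batch 1. Neuron content as the whole source is argued against by a slope of 0.94 between fold changes with and without the neuron score, all 65 keeping their direction. With the score 16 of the 65 stayed called, while the median absolute log2 fold change went from 0.59 to 0.54 over all 65 and the median SE was 0.12 before and after, so many calls were near the threshold. The batch term as the source remains open: the slope of 1.04 within batch 2 rests on 1 double heterozygous library, without which 1 gene was called, and without the batch term the slope was 0.70. A genotype effect is a hypothesis that these data raise and cannot settle.

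Neither targeted gene was called lower in the libraries labelled homozygous for it, although Dlx5 stood at 62.6 CPM against 69.4 in wild type, −0.15 on the log2 scale without the batch term. That the libraries labelled Kat6a homozygous were wild type is argued against by the 222 genes that separated them. For those labelled Dlx5 homozygous, Dlx6os1 at −0.82 does not settle the question, since this comparison rests on the batch term. Dlx6os1, chosen after the result was seen, had its smallest adjusted p, and it also fell in the libraries labelled Kat6a homozygous (−2.10). Dlx5 homozygous labelled and Dlx5 heterozygous libraries differed in 0 genes. A deletion that leaves most of the counted transcript may account for the levels of both targeted genes. Whole-gene counts (log2 fold change of Dlx5 0.0297) cannot tell, since exon counts were not used here.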

How the results depend on the processing

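Length-corrected offsets, the neuron score as covariate, removal of neuron-rich libraries and, for lists, removal of wild type replicate 4 were chosen after seeing the data. Corrections combined with a left-out library or the block, and fits of Kat6a homozygous labelled against Kat6a heterozygous libraries, were too, as was another choice of genes for the dose slope, with which that of Dlx5 (0.526) was 0.188. For the 71 called values of named genes, 2057 values under alternatives kept direction and call, 478 kept direction and lost the call and 0 reversed. Most of these values came from fits with 1 library left out, many of which dropped a library of neither group compared. The 71 values were selected as called, so the lack of reversals is no independent support. In double heterozygous libraries, 22 of 24 lost the call with only the groups compared, 22 of 25 without the batch term and 15 of 25 with the neuron score. In Kat6a homozygous labelled libraries, 16 of 37, 1 of 39 and 0 of 39 did. Where values moved, the cause was not tested. DESeq2 called 80 genes for Kat6a heterozygous, 31 for Dlx5 heterozygous, 185 for double heterozygous and 38 for Dlx5 homozygous labelled libraries. limma voom called 144 for Kat6a homozygous labelled, 132 for double heterozygous, 17 for Dlx5 homozygous labelled and 0 for the non-additive term. Without the batch term double heterozygous libraries gave 10, and Dlx5 in libraries labelled Dlx5 homozygous reversed to −0.15. Within batch 2, with fewer samples, counts were 98 (Kat6a homozygous labelled), 1 (Kat6a heterozygous), 9 (double heterozygous) and 6 (non-additive), the last 2 with 1 double heterozygous library. Length-corrected offsets gave 13 for Dlx5 homozygous labelled and 2 for the non-additive term. Without wild type replicate 1, Kat6a heterozygous libraries gave 14 with length-corrected offsets and 297 with the neuron covariate. The neuron covariate gave 16 for double heterozygous and 19 for Dlx5 homozygous labelled libraries. Without neuron-rich libraries counts were 83 (Kat6a homozygous labelled), 7 (Dlx5 heterozygous), 138 (double heterozygous), 4 (Dlx5 homozygous labelled) and 0 (non-additive). With only the groups compared they were 64 (Kat6a homozygous labelled), 10 (double heterozygous) and 0 (non-additive). Batch 2 alone and only the groups compared could not be run for Dlx5 homozygous labelled libraries.

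With 1 library left out, counts ran from 122 to 444 for Kat6a homozygous labelled, 0 to 196 for Kat6a heterozygous, 0 to 1 for Dlx5 heterozygous, 1 to 169 for double heterozygous, 0 to 16 for Dlx5 homozygous labelled libraries and 0 to 1 for the non-additive term. Dlx5 in libraries labelled Dlx5 homozygous ran from −0.0198 to 0.0867, and 6 of the 24 values had the opposite sign.

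The overlap of Kat6a and Dlx5 homozygous labelled calls (3) was 12 by DESeq2, 5 without batch, 5 with the block, 5 length-corrected, 6 with the covariate, 1 without neuron-rich libraries and 0 to 5 with 1 library left out. That of Kat6a homozygous labelled and double heterozygous calls (18) was 50 by DESeq2, 10 by voom, 8 without batch, 2 within batch 2, 7 with the covariate, 7 without neuron-rich libraries, 1 with only the groups compared and 1 to 54 with 1 library left out. That of Dlx5 homozygous labelled and double heterozygous calls (6) was 27 by DESeq2, 13 by voom, 3 without batch, 10 length-corrected, 3 without neuron-rich libraries and 0 to 13 with 1 library left out.

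Lists called for Kat6a homozygous labelled libraries (6) were 3 with an estimated correlation, 12 without wild type replicate 4 and 10 by fry's mixed test. For Kat6a heterozygous (8) they were 0 with an estimated correlation and 1 by either fry test. For Dlx5 heterozygous (5) and the non-additive term (8) they were 0 by all 3. For double heterozygous (9) they were 0 with an estimated correlation, 3 by fry's directional test, 4 without batch and 5 with the covariate. For Dlx5 homozygous labelled (13) they were 0 with an estimated correlation, 0 by fry's directional and 7 by its mixed test, and 7 without batch.

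Same-numbered libraries correlated at 0.10 on average (lowest −0.50, 28 of 60 pairs over 0.1), and 11 of 24 correlated best with their own number. The numbers were taken to pair only Kat6a homozygous labelled with wild type and with Kat6a heterozygous libraries, and correlations between differently numbered libraries leave that pairing uncertain. The replicate block gave 292, 0, 0, 46, 8 and 0 genes for Kat6a homozygous labelled (217 of the 222 among them), Kat6a heterozygous, Dlx5 heterozygous, double heterozygous, Dlx5 homozygous labelled and non-additive, the last moved from 1. For Kat6a homozygous labelled libraries it ended the calls of the endothelin and myogenic lists (1 list called with an estimated correlation) and no other call of a list at the preset correlation or of a named gene, and gave 434 genes with length-corrected offsets. Against Kat6a heterozygous libraries (93) it gave 106, and with only these groups 334 (32 without the block).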

Other observations

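The comparisons between mutant groups, the tests of genes near the targeted loci and those of ribosomal protein genes, except the one on their median, were chosen after the result was seen.

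Mutant groups were also compared with each other, in contrasts that hold no wild type library. Dlx6os1 was lower in double heterozygous than in Kat6a heterozygous libraries, with a log2 fold change of −0.57 (SE 0.10, edgeR adjusted p = 0.0412, 4 genes called) and than in Dlx5 heterozygous libraries, with −0.73 (SE 0.10, edgeR adjusted p = 0.00261, 2 genes called). It was lower in Kat6a homozygous than in Dlx5 homozygous labelled libraries, with −1.29 (SE 0.14), with 59 genes called, 15 higher and 44 lower, although these groups share no batch. The libraries labelled Dlx5 homozygous and the Dlx5 heterozygous libraries differed in 0 genes by edgeR, with 1565 at an unadjusted p under 0.05, and the single heterozygotes in 0, with 846 (no other tool was run). Dlx5 homozygous labelled and double heterozygous libraries differed in 0 genes over all libraries (1042 at an unadjusted p under 0.05). Within batch 1 alone, 4 against 3 libraries, they differed in 131 of 14074, 7 higher and 124 lower in the former, where neuron and glia scores also separate the groups (−1.59 to −1.19 against 0.75 to 1.89).

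In the libraries labelled Kat6a homozygous all 12 erythroid markers tested were positive (median 0.31, 0 called, adjusted p = 0.161), and maxillary patterning genes went both ways (1 rose and 4 fell of 16, 3 and 5 adjusted over the list alone, adjusted p = 0.161).

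Ribosomal protein genes are short and have many pseudogene copies, so their counts are uncertain. Of 81, 12 were called lower in the libraries labelled Kat6a homozygous, against 142 of 14425 other genes (Fisher's exact test, p = 5.01e-11). Genes are not independent replicates, so this p does not measure the spread between embryos. A gene length trend of wild type replicate 4 may account for their median, which went from −0.09 to −0.0365 with length-corrected offsets, while 8 of the 12 stayed called and 4 were called without that library, which leaves the calls open. With the replicate block the median went from −0.0924 to −0.0427 and 9 of the 12 stayed called. In Kat6a heterozygous libraries 81 of 81 were negative (median −0.20, −0.11 without wild type replicate 4 and −0.0945 with length-corrected offsets) and 0 were called. Against the same wild type libraries, 64 of 81 were negative in Kat6a homozygous labelled, 71 in Dlx5 heterozygous, 72 in double heterozygous and 71 in Dlx5 homozygous labelled libraries. In double heterozygous libraries 6 were called lower, 1 with length-corrected offsets and 0 without wild type replicate 4.

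Flanking chromosome carried with a targeted allele could change genes near it. Within 5 Mb of Kat6a 1 of 61 genes, Zmat4, was called in the libraries labelled Kat6a homozygous, 1.64% against 1.53% elsewhere (Fisher's exact test, p = 0.61). Within 5 Mb of Dlx5 1 of 29 genes, Dlx6os1, was called in the libraries labelled Dlx5 homozygous, 3.45% against 0.0484% elsewhere (Fisher's exact test, p = 0.0159). With 1 called gene near each locus, neither test decides. Ptprz1 (22875315 to 23052916) and Creb5 (53287226 to 53700364) lie further away on chromosome 6, which carries Dlx5. Both were called in the libraries labelled Dlx5 homozygous, and an effect of flanking chromosome on them was not tested. Mean Ptprz1 CPM was 14.7 in wild type, 14.6 in Kat6a heterozygous and 11.2 in Kat6a homozygous labelled libraries. It was 10.6 in Dlx5 heterozygous, 9.19 in double heterozygous and 8.08 in Dlx5 homozygous labelled libraries. Dlx6os1 also fell and Creb5 also rose in the libraries labelled Kat6a homozygous, which carry no mutant Dlx5 allele by their labels.

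Kat6a heterozygous replicate 3 had 87 counts of Xist (7.55 CPM), whereas the other 23 libraries had at least 963 CPM, and all embryos are labelled female. The libraries' counts of 4 Y-linked genes are 0 there. With wild type libraries split 2 and 2, calls ran from 76 to 1291 for Kat6a homozygous labelled and from 0 to 1483 for Kat6a heterozygous libraries.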
